A study of Mus musculus with 2 samples.

How the data were processed

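Small RNA of embryonic mouse liver at day 13.5 was sequenced as 2 libraries, which the labels number as biological replicates 1 and 2 from separate biosamples. Each biosample pooled male and female embryos of the strain B6NCrl, and both had been size selected for RNA below 30 bases, per the labels. The labels name 1 group and no treatment, so no comparison between groups exists and none was made.

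The deposited tables hold raw read counts per gene on the mouse build mm10 with GENCODE annotation M4, per the labels and the deposited lists of files. The aligner and the counting program are not given in the sources used here. Each table gave 3 counts for each of 1973 genes: reads on the strand of the gene, reads on the opposite strand, and both together. The last equalled the sum of the other 2 for all 1973 genes in both libraries. Separate rows gave reads that were unmapped, mapped to several places or fell in no gene, and these were left out of library totals and tests. In replicate 1, 36.7% of 7671547 reads mapped to several places, 19.6% were unmapped and 5.72% fell outside the counted genes. In replicate 2, these were 32.0%, 24.2% and 5.64% of 12554684 reads. Reads that mapped to several places were not assigned to genes in these tables, so the counts of a microRNA with identical copies in the genome are uncertain. A gene row combines all reads of a hairpin, and the 2 arms cannot be told apart.

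The counts on the strand of the gene were used, since ligation of adapters to small RNA keeps the strand. They came to 2607403 in replicate 1 and 4286742 in replicate 2. Counts were scaled to CPM, counts relative to these totals times 1000000. A count of 3, the upper limit that a count of 0 allows, corresponded to 1.15 CPM in replicate 1 and 0.700 CPM in replicate 2, which does not limit the level of a gene with copies. Intervals and limits cover counting error only, since no molecular identifiers enter these counts. A gene counted as detected with at least 10 counts in each library. Gene names, coordinates and host genes came from GENCODE M21, which is on the same build (GRCm38, or mm10) but later than the annotation used for counting. Of the 1973 genes, 1894 matched an M21 gene by identifier, and the other 79 held 6 reads in total. A gene was called uncertain if its hairpin shared a word of 20 bases with a microRNA gene at another, non-overlapping locus in M21, on either strand. This replaced a planned search of the genome sequence, which was not used here.

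Levels are given as mean ± SD of the 2 libraries. No exact test over 2 libraries can give a two-sided p below 0.5, so levels and ratios of gene lists carry no p-value. The 17 lists of cell-type markers, families and clusters were fixed before the data were examined, as were the tests, the detection limit and the rule for naming genes. That rule took the 20 genes with the highest mean CPM, up to 4 members of each list, and the 3 genes with the largest difference in each direction between the libraries among those with an adjusted p under 0.05 and at least 100 counts. The position of each list was described by the percentile of its median gene among 10000 random lists of equal size drawn from all 1973 genes. Neighbouring microRNA genes were compared with a two-sided permutation test of 100000 shuffles on log2(CPM + 1). The libraries were compared gene by gene with a two-sided exact binomial test of the split of counts against the split of the totals, with Benjamini-Hochberg adjustment over the genes with a count. That test compares the 2 libraries and no conditions. The spread between replicates beyond counting error was taken as the square root of the common dispersion from edgeR 4.0.16 with TMM scaling and an intercept-only design, with an interval from 200 resamples of genes. DESeq2 1.42.0 gave alternative size factors. The other steps used Python 3.11.15 with scipy 1.17.1.

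The library test was tested on simulated Poisson counts for 668 genes with a count, of which 200 were changed. It called 92% of genes changed by 1.5 times, 98% of those changed by 2 times and 1.07% of unchanged genes. These shares hold for the simulated counts, which held no spread beyond counting error. They do not carry over to the libraries, which had such a spread, nor to rare genes in the libraries. There Mir199a-2, at 1.52-fold on 46 and 115 counts, was not called (adjusted p = 0.0675, exact binomial test). For simulated libraries of 1973 genes with a biological coefficient of variation of 10%, 20% and 30%, the edgeR estimate averaged 9.89%, 19.6% and 29.2%. The alternatives were counts without regard to strand, other detection limits, other scalings, other distances between neighbours and each library alone.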

Results

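The microRNA population of the mouse liver at embryonic day 13.5 was profiled in 2 biological replicates. At this age the liver is the main site of blood formation in the embryo and also holds immature hepatocytes, endothelium and mesenchyme. Replicate 1 gave 2607403 counts on the strand of annotated microRNA genes and replicate 2 gave 4286742. At least 10 counts in each library were found for 367 of 1973 genes, which were taken as detected.

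By counts on the strand of the gene, Mir122, Mir126a, Mir17 and Mirlet7g were the 4 most abundant microRNA genes. Reads that mapped to several places, 36.7% in replicate 1 and 32.0% in replicate 2, are not in this ranking. The places of genes with copies are therefore uncertain. Mir122 (ENSMUSG00000065402.1), the hallmark microRNA of hepatocytes, was the most abundant gene at 79994 ± 213 CPM (SD, n = 2). It lies on chromosome 18 at 65248861 to 65248926 (mm10), in an annotated exon of the non-coding gene AC157910.3. Mir126a, an endothelial microRNA hosted by Egfl7, followed at 56024 ± 2091 CPM and stayed below Mir122 in both libraries. Its hairpin is on chromosome 2 at 26591357 to 26591429. Mir17 (chromosome 14, 115043671 to 115043754, in an exon of Mir17hg) reached 49109 ± 6186 CPM, and Mirlet7g (chromosome 9, 106178840 to 106178927, in an intron of Wdr82) reached 47117 ± 4690 CPM. These 2 could not be ranked, because Mir17 was the lower in replicate 1 (44735 against 50434 CPM) and the higher in replicate 2 (53483 against 43801 CPM).

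The next genes were Mir335, in an intron of the imprinted gene Mest, at 40942 ± 3741 CPM and Mir26b, in an intron of Ctdsp1, at 38964 ± 3913 CPM. Mir322 on chromosome X followed at 28333 ± 252 CPM. Mir20a, Mir99a and Mir21a completed the first 10 by mean at 24782 ± 2622, 24161 ± 1868 and 23818 ± 796 CPM. With both strands counted, the loci of Mir142b and Gm24321 would take places 5 and 8, at 41371 and 27617 CPM, so the first 10 would differ. Places 11 to 20 by mean were taken by Mir411, Mir487b, Mir130a, Mirlet7i, Mir30e, Mir451a, Mir93, Mir143, Mir127 and Mir431, with means from 16129.8 to 21670.0 CPM. The place of Mir451a is not firm: at 10750 CPM it lay below the other 19 genes in replicate 1, and at 26342 CPM above Mir99a and Mir21a in replicate 2. Among these, Mir411 and Mir487b shared a word of 20 bases with another locus (Mir758 and Mir376b), so their counts are uncertain. The first 10 genes held 41.3% ± 0.833 of all counts on the strand of the gene (SD, n = 2) and the first 20 held 60.4% ± 0.309.

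**Figure D1:**
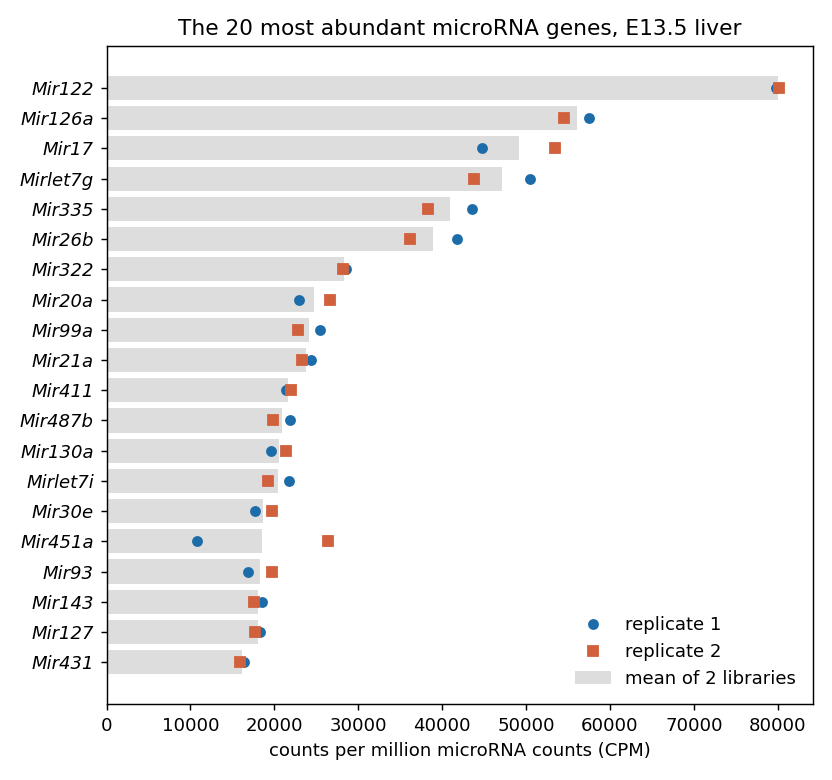
Mean CPM (bars) of the 20 most abundant microRNA genes by counts on the strand of the gene, with replicate 1 as circles and replicate 2 as squares. Mir122 is highest at 79994 CPM, and Mir451a shows the widest gap between the libraries, 10750 against 26342 CPM.

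Marker microRNAs of the cell types expected in this tissue were compared as summed levels of lists. The lists hold different microRNAs and were not calibrated to cells, so their sums and ratios do not give shares of cell types. The hepatocyte list held 8.50% ± 0.0574 of counts (SD, n = 2), the endothelial list 5.67% ± 0.210, the erythroid list 2.55% ± 1.06, the mesenchymal and smooth muscle list 2.45% ± 0.0699 and the leukocyte and lymphoid list 1.31% ± 0.0562. With counts from both strands the leukocyte and lymphoid list held 5.31% ± 0.0571, since the reads opposite Mir142b join it. Words are shared with another locus by 6 of 11 counted leukocyte genes, 3 of 8 mesenchymal genes and 2 of 6 hepatocyte genes, so their counts are uncertain. Single genes carried most of these sums. Mir122 made up 94.1% of the hepatocyte list, with Mir192 at 2771 ± 195 CPM, Mir194-2 at 1128 ± 129 CPM and Mir148a at 1079 ± 35.5 CPM. Mir126a made up 98.8% of the endothelial list, with Mir221 at 438 ± 4.13 CPM. Mir143, which is enriched in smooth muscle and other mesenchymal cells, stood at 18031 ± 716 CPM, ahead of Mir140 at 3977 ± 109 CPM and Mir214 at 2023 ± 141 CPM.

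Among blood cell microRNAs, Mir451a (chromosome 11, 78073170 to 78073241) and Mir144 (78073005 to 78073070), which are made from a shared primary transcript in red cell precursors, stood at 18546 ± 11026 and 6139 ± 377 CPM. Mir486 stood at 827 ± 10.1 CPM, and 1 of the 4 listed erythroid genes was not analysed here. The check for copies did not cover genes that overlap at the same locus, so a copy of Mir486 there would go unseen. Mir223, a myeloid microRNA, stood at 10092 ± 100 CPM and led the leukocyte list on the strand of the gene, followed by Mir342 at 1641 ± 370 CPM. Mir181a-1 at 602 ± 93.3 CPM and Mir181b-2 at 277 ± 149 CPM share words with their copies Mir181a-2 and Mir181b-1. The erythroid list lay below the hepatocyte list by a log2 ratio of -1.80 ± 0.61 (SD, n = 2), a 4.70-fold difference in replicate 1 and a 2.58-fold difference in replicate 2. That order rests on Mir122: without it, an alternative chosen after seeing the data, the log2 ratio turned to 2.29 ± 0.52. Without Mir451a it was -3.61 ± 0.09. Against the leukocyte list the erythroid log2 ratio was 0.90 ± 0.56. The order of these 2 lists was not firm: the log2 ratio was -1.28 ± 0.63 with counts from both strands, which add the reads opposite Mir142b to the leukocyte list, and -0.91 ± 0.14 without Mir451a.

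Clusters and families associated with progenitors and proliferation differed widely in level. The miR-17-92 cluster on chromosome 14, a growth-promoting polycistron, held 9.03% ± 0.867 of counts, and its 6 members spanned a wide range. Mir17 and Mir20a led, Mir92-1 stood at 8365 ± 442 CPM (with a copy, Mir92-2) and Mir18 at 7914 ± 303 CPM, while Mir19b-1, which shares a word with Mir19b-2, was at 43.7 ± 2.75 CPM. The related miR-106b-25 cluster within Mcm7 summed to 30016 ± 1412 CPM, with Mir93 at 18259.7 ± 2017 CPM, Mir106b at 10801 ± 600.0 CPM and Mir25 at 954 ± 5.09 CPM. The X-linked miR-106a-363 cluster held 0.0901% ± 0.00312, with Mir92-2, which shares a word with Mir92-1, at 266 ± 22.8 CPM and Mir106a at 240 ± 22.03 CPM. These 2 changed order between the libraries. The progenitor list of miR-99, miR-100, miR-125, miR-10 and Mir196b genes held 4.93% ± 0.279, led by Mir99a, Mir99b at 9201 ± 247 CPM and Mir10a at 8249 ± 386 CPM. The let-7 family, whose members oppose proliferation, held 7.93% ± 0.730, led by Mirlet7g and Mirlet7i, with Mirlet7d at 5565 ± 495 CPM and Mir98 at 3815 ± 302 CPM. Of its 10 counted members, 5 share words with another locus, and 4 further members were not analysed here.

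Imprinted microRNAs of the Dlk1-Dio3 cluster had the highest sum of the 17 lists and also the most genes counted. Their median gene, at 1902 CPM, lay below those of the miR-106b-25 cluster (10801.5 CPM), the miR-17-92 cluster (8140 CPM) and the erythroid list (6139 CPM). The Dlk1-Dio3 cluster, maternally expressed and on chromosome 12, summed to 169531 ± 1957 CPM (SD, n = 2), and all 37 counted members were detected. Another 6 of its 43 listed genes were not analysed here. Reads at the positions of Mir409, Mir376a, Mir299a and Mir380 in this cluster lie outside the sum. They fell opposite Gm24321, Gm25252, Mir299b and Gm25750, at 27617, 9970, 4115 and 2602 CPM with both strands counted. The sum with both strands, 151857 CPM, leaves them out too. On the strand of the gene, Mir411 and Mir487b led, followed by Mir127 at 18018 ± 391 CPM and Mir431 at 16129.8 ± 328 CPM. The reads opposite Gm24321, 72806 and 144711, exceeded those of Mir411, 55821 and 94014, in both libraries. At the H19 and Igf2 locus, Mir483, hosted by Igf2, stood at 2828 ± 72.2 CPM and Mir675, which is processed from H19, at 189 ± 14.0 CPM.

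Counts of markers of other tissues were low but mostly present. The epithelial list held 0.343% ± 0.0356 of counts, led by Mir429 at 1428 ± 89.4 CPM, and the pancreatic list held 0.173% ± 0.00882, of which Mir375 made up 99.0%. The striated muscle list held 0.105% ± 0.0262, led by Mir206 at 697 ± 247 CPM and Mir499 at 255 ± 30.7 CPM. Of its 9 counted genes, 5 share words with another locus, among them Mir133a-1 and Mir133a-2, which had no counts, so the level of this list is uncertain. The pluripotency list held 0.0524% ± 0.00621, led by Mir302a at 124 ± 20.4 CPM, and 4 of its 12 counted genes share words. The neural list was lowest at 0.0294% ± 0.000207, led by Mir128-1 at 134 ± 25.7 CPM. In it 4 of 11 counted genes, Mir9-2 and the 3 Mir124a genes, had no counts in either library. All 11 neural genes share words with another locus, so their counts, including those of 0, are uncertain and set no limit on their levels. The median gene of each of the 17 lists lay at or above percentile 90.0 of random lists of equal size, the neural list at 99.3, but these were drawn from all 1973 genes, of which 367 were detected, so the percentiles do not set tissues apart.

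**Figure D2:**
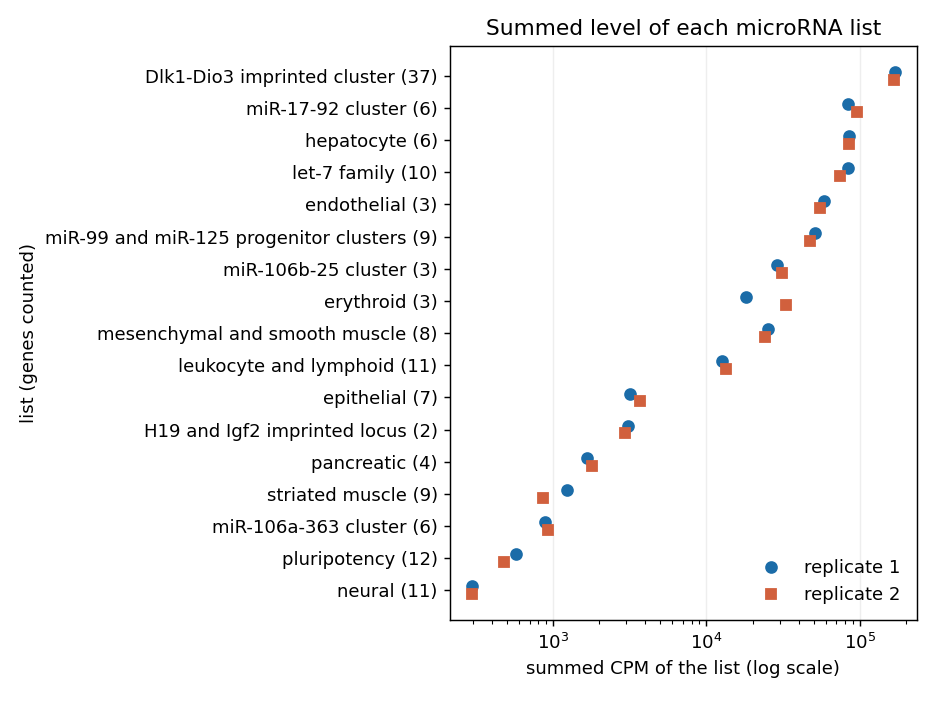
Summed CPM of each of the 17 lists on a log axis, with replicate 1 as circles and replicate 2 as squares, and the number of genes counted in brackets. The Dlk1-Dio3 cluster is highest at 170915 and 168147 CPM, the neural list is lowest at 296 and 293 CPM, and the erythroid list is among those with visibly separate libraries at 17989 and 33035 CPM.

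Because many microRNAs are processed from shared primary transcripts, the levels of neighbouring genes were compared. Among 114 pairs of detected neighbours within 10 kb on the same strand, the median absolute difference was 3.20 in log2(CPM + 1), against 3.67 after shuffling levels over the 367 detected genes. The permutation test did not separate these values (two-sided p = 0.26). Mir144 and Mir451a are such a pair, at 6139 and 18546 CPM. Mir17 and Mir19b-1 lie farther apart in level, at 49109 and 43.7 CPM. They are not direct neighbours, and Mir19b-1 shares a word with Mir19b-2, so its count is uncertain. Genes are not independent replicates, and the uncertain counts of copies enter these differences.

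The replicates were then compared with each other. Over the 367 detected genes, log2(CPM + 1) of the 2 libraries correlated with Pearson's r = 0.995 and Spearman's rho = 0.991 across genes, which are not independent replicates. The median difference was 1.13-fold, and 319 of 367 genes lay within 1.5-fold. The biological coefficient of variation from edgeR was 13.1% (95% interval over resampled genes 10.3% to 15.8%). The exact binomial test called 143 of 711 genes with a count at an adjusted p under 0.05, 61 higher and 82 lower in replicate 2, so the libraries are not the same library deposited again. With TMM library sizes the split was 72 higher and 63 lower. Of the 143 genes, 26 differed by at least 1.5-fold, 13 in each direction. Some of these were below the detection limit. Among the lower genes, Mir678, Mir697, Mir6913 and Mir8103 had 5 to 7 counts in replicate 1 and 0 in replicate 2. Among the higher genes, Mir103-1 had 5 and 30 counts.

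Among called genes with at least 100 counts in total, Mir451a had the largest difference upward, higher in replicate 2 by 1.29 in log2 (95% counting interval 1.27 to 1.31), from 28029 counts in replicate 1 to 112923 in replicate 2. Mir181b-2, which has a copy, was higher in replicate 2 by 1.16 in log2 (adjusted p = 1.04e-56, exact binomial test with Benjamini-Hochberg adjustment). Mir208a, a heart microRNA in an intron of Myh6, was higher by 0.98 on 25 and 81 counts (adjusted p = 0.0144, exact test). In the other direction, Mir92b fell by 1.37 in log2 (adjusted p = 5.27e-37, exact test), Mir204, in an intron of Trpm3, fell by 1.01 on 65 and 53 counts (adjusted p = 0.00136, exact test), and Mir206, a skeletal muscle microRNA, fell by 0.74 (adjusted p = 6.95e-64, exact test). Of the 3 erythroid genes counted, 2 were called, Mir451a as higher and Mir144 as lower, with the adjustment over all genes and adjusted over the list alone. Of 37 Dlk1-Dio3 genes, 19 were called, 6 higher and 13 lower, and 21 were called adjusted over the list alone. Over all 711 genes, 20.1% were called. The median log2 difference of this list was only -0.027, and genes with many counts were called at small differences, such as Mir411 at 1.02-fold.

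**Figure D3:**
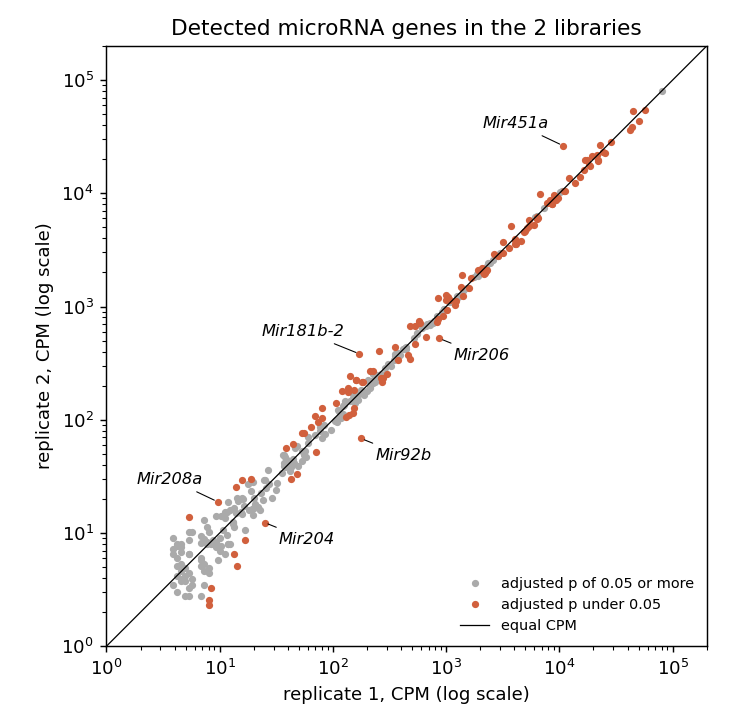
CPM of the 367 detected genes in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with genes at an adjusted p under 0.05 in the exact binomial test in orange and the line of equal CPM. Mir451a lies farthest above the line among abundant genes and Mir92b, at 177 against 68.4 CPM, lies well below it.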

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

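The tests in this part were chosen after the results were seen. A signal appeared in data outside the counts used above: 10.4% of microRNA counts in replicate 1 and 10.5% in replicate 2 lay on the strand opposite the counted gene. They came almost entirely from 10 genes with at least 100 opposite-strand counts in each library, which together held 99.8% of them in both libraries. Each of the 10 overlaps a microRNA gene that M21 annotates on the other strand and that was not analysed here as a row of its own. The counts opposite Mir142b, where M21 places the blood cell gene Mir142 (chromosome 11, around 87756841 to 87756955), were 122527 in replicate 1 and 194599 in replicate 2, against 1 and 4 on its own strand. With both strands counted this locus would rank at place 5, at 41371 ± 1059 CPM (SD, n = 2). Opposite Gm24321, at the position of Mir409, they were 72806 and 144711. Opposite Gm25301, at Mir378a, they were 30787 and 44693. Opposite Gm25252, at Mir376a, they were 29842 and 46377. Opposite Gm24083, at Mir191, they were 18545 and 31134. Opposite Mir299b, at Mir299a, they were 12220 and 19253. Opposite Gm25750, at Mir380, they were 8167 and 11482. Opposite Gm25927, at Mirlet7e, they were 5125 and 8897. Opposite Mir497b, at Mir497, they were 796 and 1264. Opposite Gm24111, at Mirlet7f-1, they were 227 and 408.

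Loss of strand in the library preparation is argued against, since the median share of opposite-strand counts over 377 genes detected on either strand was 0% in both libraries, and 324 of them had no such count. Reads of the annotated gene on the other strand remain as a candidate explanation, since at least 99.95% of opposite-strand counts lay at genes with such a partner in M21. If so, the levels of Mir142 and its like are missing from the strand-specific lists. No biological explanation was tested, since the design has 1 group.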

How the results depend on the processing

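With at least 1 count in each library in place of 10, 559 genes were detected in place of 367, and the other alternatives gave 294 to 408. With counts from both strands, the first 10 genes held 39.6% in place of 41.3%, and the erythroid to leukocyte log2 ratio turned from 0.90 to -1.28. That reversal comes from the reads opposite Mir142b, which join the leukocyte list. Without Mir451a, a choice made after seeing the data, this ratio turned to -0.91, so its direction rests on that gene. The erythroid to hepatocyte ratio kept its direction there and moved from -1.80 to -3.61. Without Mir122, likewise chosen after seeing the data, it turned to 2.29, so its direction rests on Mir122. Leaving out each library in turn changed neither direction: the erythroid to hepatocyte ratio ran from -2.23 to -1.37 and the erythroid to leukocyte ratio from 0.50 to 1.29. With 2 libraries, leaving 1 out cannot move a mean by more than 1 SD, so list levels are given as folds: they moved by up to 1.29-fold without replicate 1 and 1.42-fold without replicate 2. Of 51 list levels under both strands, TMM and DESeq2 scaling, 13 moved by more than 1 SD, all with counts from both strands. The farthest was the leukocyte list, by 4.06-fold to 53092 CPM. The others fell because the total grew, in replicate 1 from 2607403 to 2909040 counts. The hepatocyte list thus went from 84984 to 76109 CPM. The neighbour test gave p from 0.1 to 0.38, and the count of genes that differed between the libraries ran from 135 to 153. The biological coefficient of variation ran from 12.3% to 13.4%. No paired analysis was possible because the labels give 1 group. The planned restriction to genes unique in the genome was not run, and shared words between hairpins took its place. With 2 libraries, depth limits the rarer genes: 10 counts in replicate 1 are the least that counts as detected.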

Other observations

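The tests of Mir451a and of gene copies in this part were chosen after the results were seen. The genes of this paragraph lie outside the lists and were chosen after their values were seen. Mir15a and Mir16-1, antiproliferative microRNAs within Dleu2, stood at 8572 ± 324 and 6256 ± 183 CPM (SD, n = 2), above their relatives within Smc4, Mir15b at 3056 ± 136 and Mir16-2 at 1078 ± 101 CPM. The 2 Mir16 genes are copies of each other, so their counts are uncertain. On chromosome X, Mir322 at 28333 ± 252 CPM stood far above its neighbours Mir351 at 3423 ± 383 CPM, Mir542 at 955 ± 4.76 CPM and Mir503 at 690.1 ± 15.4 CPM. Of the miR-30 family, Mir30e at 18670.0 ± 1445 CPM and Mir30a at 12889 ± 905 CPM were highest, and Mir30b was at 140 ± 18.97 CPM.

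Mir451a was 2.45-fold higher in replicate 2, while Mir144 from the same cluster differed by -0.13 in log2. A larger erythroid share of RNA in that library, as the source of the whole difference, is argued against, because it should raise Mir144 and Mir486 alike. Their mean log2 difference was -0.075 (95% counting interval -0.116 to -0.034), below the bound of 0.32 set from the 1.29 of Mir451a. That interval leaves out the spread of genes between the libraries, a residual SD of 0.41 in log2 over the 366 other detected genes. A smaller rise in erythroid RNA is therefore not excluded. Copies at the locus of Mir486 were not checked, but Mir144, which shares no word with another locus, was lower by itself. A linear trend with GC content of the hairpin is argued against for Mir451a. Over 366 other detected genes the slope was -0.0071 in log2 per 10 percentage points (95% interval -0.049 to 0.035). Mir451a has a GC content of 47.2%. Its difference was 1.29 before this correction and 1.30 after it, 3.17 residual SD from the line. The rule written for this test left it undecided where the slope interval holds 0. Slopes in that interval are nevertheless too small for a difference of 1.29. Also open is a difference in capture or trimming of this particular RNA, or in its processing, which these counts do not resolve. No biological explanation named by the design was available to test.

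Reads shared between copies may explain low counts within clusters. Mirlet7c-1 was at 38.0 ± 1.68 CPM beside Mir99a at 24161 ± 1868 CPM, and Mir19b-1 was at 43.7 ± 2.75 CPM beside Mir20a. In that cluster 2 genes go the other way: Mir19a, which shares no word, was also low at 131 ± 7.92 CPM, and Mir92-1, which shares one, stood at 8365 ± 442 CPM. In 41 pairs of neighbours of which 1 shares a word with another locus, the sharing member was lower in 25, with a median log2 difference of -1.65 (two-sided permutation p = 0.11). The explanation stays open, since that test does not pass and reads mapping to several places were not assigned to genes.

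A hypothesis written before its test was that the libraries differ by mature sequence, as a ligation bias would give. Family members at separate loci would then shift together. In 90 such pairs the median absolute difference of log2 differences was 0.231 against 0.229 after shuffling (two-sided permutation p = 0.96, adjusted over 2 tests 0.96). The contrasting hypothesis, that loci differ in transcription, was tested in 88 pairs of neighbours from different families: 0.164 against 0.227 after shuffling (permutation p = 0.036, adjusted 0.072). Neither passed after adjustment. The first test cannot decide on mature sequence. Families were set by the number in the gene name, so pairs such as Mir30b and Mir30c-1 or Mir181c and Mir181b-2 need not share one. Pairs of copies, such as Mir181a-1 and Mir181a-2, have uncertain counts.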
